A study of Capra hircus with 20 samples.

How the data were processed

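Small RNA was sequenced from hypothalamus of Jining grey goats, a Chinese breed known for early puberty and large litters, at 1, 60, 120 and 180 days after birth. Each of the 4 stages had 5 biological replicates, per the design text of the series, giving 20 libraries. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with the NEBNext small RNA kit. The submitters' processing notes name Bowtie, without a version. The genome build, the miRNA catalogue, the read counter and the tool behind the numbered miRNA predictions are not given in the sources used here.

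The authors deposited 1 table of 683 miRNAs in RPM, the reads of a miRNA scaled to a common library total. Of these, 407 had a known miRNA name and 276 were numbered predictions. Its column names call the unit TPM, but the values were not divided by length: low values in each column were whole multiples of 1 step, and each column fell short of the full RPM total by at most 16.2. The unit was therefore taken as RPM of the miRNA reads. The smallest sum of a miRNA over the 20 libraries was 1.01, so the table appears to leave out miRNAs below a sum of 1. Dividing by the step returned whole reads for 100% of the values below 1000 reads, within a tolerance of 0.1 read. The recovered depth ran from 4017937 to 8324880 miRNA reads per library, with a median of 6978196. A floor of 3 reads corresponds to between 0.360 and 0.747 RPM; it covers counting error only, since PCR copies are not independent molecules. No 2 libraries of a stage agreed within sampling noise: over 40 pairs the smallest chi-square per degree of freedom was 392.

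The main test was limma (version 3.58.1, R 4.3.3; eBayes with a mean-variance trend, two-sided) on log2(RPM + 1), as fixed before the data were examined. A miRNA was tested if it reached 1 RPM in at least 5 of the 20 libraries, which kept 414 miRNAs, 357 of them named and 57 numbered predictions. All 20 libraries entered 1 fit with 4 stage means and no covariate, because the labels give no batch. The 3 contrasts between neighbouring stages, day 180 against day 1, day 120 against day 1, day 180 against day 60 and an F test over the 4 stages were each adjusted by Benjamini-Hochberg at 0.05. Fold changes are on the log2(RPM + 1) scale, which understates changes of miRNAs near the floor. The median standard error was 0.518 log2 units. At that error and with the 16 residual degrees of freedom alone, a t test needs a 2.14-fold change for an unadjusted p of 0.05. limma adds 9.51 prior degrees of freedom, so the change it needs is slightly smaller.

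The text names, for the neighbouring stages and for day 180 against day 1, up to 10 known miRNAs with the largest rise and 10 with the largest fall among those past the threshold and at 10 RPM or more in the mean of at least 1 stage; when fewer passed, all are named. Members of a fixed list are named as examples of it, and the 10 most abundant miRNAs describe the data. Names outside this rule are marked as chosen after their values were seen. Members of a family with nearly identical sequences (let-7, miR-29, miR-30, miR-200, miR-17-92, miR-193) can share reads, so the split between them is uncertain.

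A set test (camera, preset correlation 0.01) was run on 20 lists fixed in advance: the let-7 family, the miR-17-92 cluster and its paralogs, the miR-29, miR-200 and miR-30 families, the miR-183 cluster, the DLK1-DIO3 imprinted cluster, puberty and GnRH-related miRNAs, and markers of neurons, oligodendrocytes and myelin, astrocytes, neural stem and progenitor cells, microglia and immune cells, erythroid cells, vessels, multiciliated cells and choroid plexus, pituitary and epithelium, skeletal and cardiac muscle, liver, and the HOX cluster of posterior tissue. The lists overlap in part: the tested astrocyte list holds every tested member of the miR-29 family. All list results were adjusted over the 20 lists of a comparison, and those of all libraries were repeated with the correlation estimated from the data. List results with a library left out used the preset correlation only. The estimated correlation was 0.306 for the let-7 family, 0.730 for miR-29, 0.179 for the astrocyte list and 0.462 for DLK1-DIO3. For these lists the preset 0.01 is therefore too low and gives p-values that are too small. Their members vary together, so counts of members in 1 direction are not counts of independent observations.

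Alternatives fixed in advance were a pseudocount of 0.1 or 5, no filter or a filter at 10 RPM, median-of-ratios or quantile scaling, no variance trend, only the 2 stages compared, the replicate number as a block, and leaving out each library in turn. On the recovered reads, edgeR's quasi-likelihood test (version 4.0.16; TMM or library size alone) and DESeq2 (version 1.42.0) were run as alternatives. The whole-tissue values carry no sequence, so GC content was not analysed here.

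The tests were tried on simulated reads drawn from the means and depths of the real libraries, with 200 miRNAs changed by 2-, 4- or 8-fold in either direction in the later stage. Each miRNA was drawn independently, so the variation that miRNAs share between real libraries is absent. The rates below hold only without such shared variation. With the changed miRNAs drawn from those below 1000 RPM, limma recovered 56.3% of the 4-fold and 87.7% of the 8-fold changes for day 60 against day 1 (422 miRNAs run). It recovered 8.82% of the 2-fold changes there, and 4 of 225 unchanged miRNAs were called. For day 120 against day 60 (426 miRNAs run), it recovered 62.1% of the 4-fold and 92.1% of the 8-fold changes. When the changed miRNAs were drawn from all levels, the most abundant ones shifted the library total: the unchanged miRNAs of the simulation of day 60 against day 1 moved by a median of -0.98 log2 units, and 47 of 221 were called lower (421 miRNAs run). This is a limit of values given relative to the library total, and the alternatives with another scaling bear on it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.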

Results

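The data are miRNA levels of the goat hypothalamus, the brain region that drives puberty through gonadotropin-releasing hormone, at 4 ages: days 1, 60, 120 and 180 after birth, with 5 animals each. Recovered depth averaged 7043460 ± 1756450 miRNA reads (SD, n = 5) on day 1, 5940159 ± 890914 on day 60, 7492170 ± 952695 on day 120 and 7178190 ± 1035220 on day 180. The most abundant miRNA was miR-9-5p, a neural miRNA, at 174740 ± 65703 RPM (SD, n = 20), or 17.5% of all reads. It was followed by miR-7-5p, abundant in neuroendocrine cells, at 8.36%, by let-7f-5p at 6.72% and by miR-143-3p of smooth muscle at 6.35%. The next were miR-26a-5p at 4.91%, miR-100-5p at 4.91%, let-7a-5p at 4.46%, let-7g-5p at 4.44%, miR-27b-3p at 4.17% and let-7i-5p at 3.30%. One library, replicate 2 of day 1, stood apart: its median Spearman correlation with the other libraries was 0.873, against 0.918 for the next lowest, and its depth of 4017937 reads was the lowest.

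The first question was which miRNAs change over postnatal and sexual development as a whole. Across the 4 stages, 8 of 414 miRNAs passed limma's F test, 6 of them named. miR-101-3p, a repressor of the Polycomb enzyme EZH2, went from 1717 ± 957 RPM on day 1 (SD, n = 5 in each stage) to 4720 ± 2879 on day 60, 9702 ± 3710 on day 120 and 11379 ± 7487 on day 180 (adjusted p = 0.00175). miR-363-3p, from a paralog of the growth-promoting miR-17-92 cluster, went from 108 ± 48.0 RPM to 29.7 ± 9.73, 27.5 ± 2.12 and 16.4 ± 3.42 (adjusted p = 0.0021). miR-449a-5p, a miRNA of multiciliated cells, went from 19.5 ± 17.7 to 1.37 ± 0.794, 2.72 ± 4.59 and 0.686 ± 0.482 RPM (adjusted p = 0.00411). miR-493-3p of the DLK1-DIO3 imprinted cluster went from 94.0 ± 57.7 to 19.2 ± 5.16, 21.1 ± 10.9 and 15.3 ± 9.12 RPM (adjusted p = 0.0134). miR-3955-3p rose from 4.68 ± 1.73 to 17.1 ± 10.5, 24.3 ± 7.77 and 19.8 ± 9.73 RPM (adjusted p = 0.0338). miR-122, the main miRNA of liver, passed at an adjusted p of 0.0439. At an unadjusted p under 0.05 there were 70 miRNAs. In 3 of the 8 the stage means lay in strict order of age, 1 upward and 2 downward; among all 414 tested, 58 (14.0%) did, 18 upward and 40 downward. The median of all log2 fold changes against day 1 itself fell with age, from -0.04 on day 60 to -0.12 on day 120 and -0.25 on day 180, so that falls are favoured in this count. The F test called 5 miRNAs without replicate 2 of day 1, 5 without replicate 3, 16 without replicate 4 and 15 without replicate 5 of that stage. The other scalings and count tests gave 28 to 90.

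**Figure D1:**
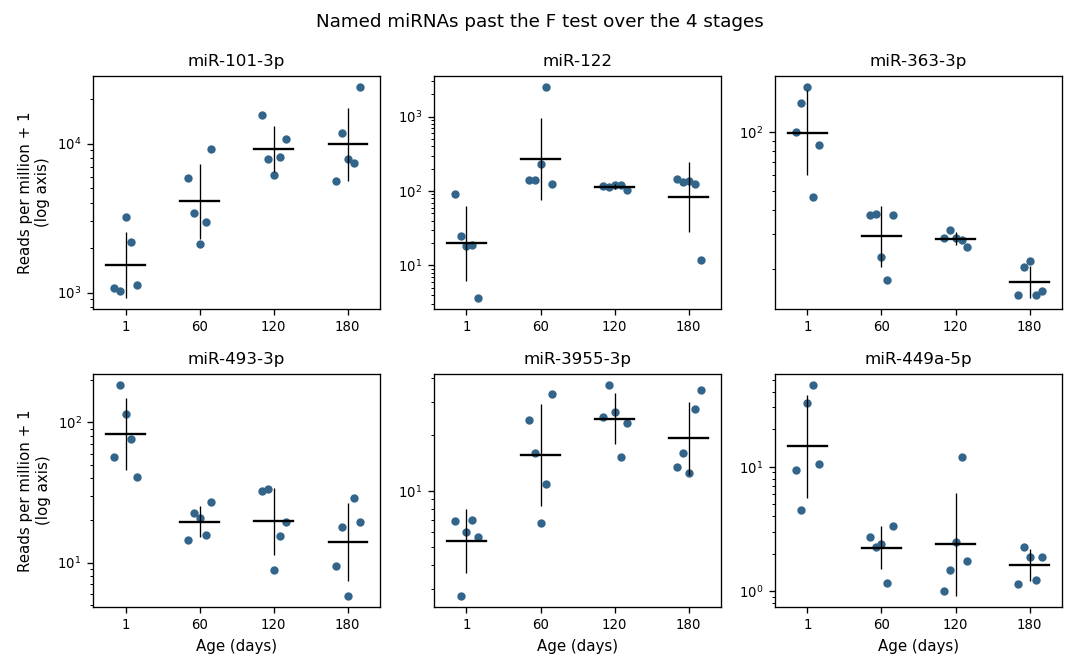
Levels of the 6 named miRNAs past the F test, in RPM + 1 on a log axis, against age in days. Each point is 1 library (5 per stage), the horizontal bar is the mean of the log2 values and the vertical line their SD. The arithmetic mean of miR-101-3p, which is not drawn, was 1717 RPM on day 1 and 11379 RPM on day 180. miR-101-3p and miR-3955-3p were not called for day 60 against day 1.

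Between day 1 and day 60 most members of the let-7 family, which accumulates as cells differentiate, lay higher on day 60. Of its 17 tested members 15 lay above 0, with a median log2 fold change of 1.04; 2 members were called higher and 7 when adjusted over the list alone. let-7c-5p rose from 5393 ± 1125 to 17012 ± 10206 RPM (SD, n = 5; log2 fold change 1.46, SE 0.42, adjusted p = 0.0494), and let-7c-3p from 8.34 ± 3.26 to 27.6 ± 8.97 RPM (1.63, SE 0.44, adjusted p = 0.0399). let-7d-5p measured 644 ± 209 and 1765 ± 485 RPM and did not pass over all miRNAs (adjusted p = 0.07). The set test gave the family an adjusted p of 1.85e-05; the adjusted p was 0.789 with an estimated correlation. With the preset correlation the family passed in 20 of 20 fits with 1 library left out; with an estimated one the call was lost. The mean over the family lay above the day-1 mean in 5 of 5 day-60 libraries.

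In all, 16 miRNAs changed between day 1 and day 60, 3 upward and 13 downward, of which 13 were named. The largest rise was that of miR-122, from 30.8 ± 34.9 to 635 ± 1066 RPM (log2 fold change 3.78, SE 0.81, adjusted p = 0.011). Replicate 4 of day 60 alone held 2540 RPM. Without it the change was 2.97 with an adjusted p of 0.0559, the upper end of a range from 1.01e-07 over all alternatives. Its companion on the liver list, miR-192-5p, measured 749 ± 410 and 729 ± 308 RPM. Among the 9 named falls, miR-449a-5p decreased to a level close to 1 RPM (log2 fold change -2.70, SE 0.59, adjusted p = 0.0112), miR-363-3p fell by 1.76 (SE 0.42, adjusted p = 0.0188) and miR-493-3p fell by 2.07 (SE 0.52, adjusted p = 0.0249). miR-99a-3p, transcribed from the same cluster as let-7c, fell by 2.38 on the log2 scale, from 22.9 ± 18.0 to 4.01 ± 3.71 RPM. miR-324-5p fell by 2.50, miR-874-5p fell by 2.07 and miR-1388-3p fell by 1.80, all at or below 103 RPM in the day-1 mean. Without replicate 2 of day 1 the change of miR-324-5p was -1.81 (adjusted p = 0.113, in a range from 5.41e-05 to 0.164 over all alternatives). At higher levels, miR-1271-5p fell from 1043 ± 375 to 343 ± 220 RPM (log2 -1.72), and miR-30a-5p from 10245 ± 5136 to 3505 ± 1481 RPM (log2 -1.54, SE 0.39, adjusted p = 0.0249). Each of these 12 miRNAs lay beyond the day-1 mean in its direction in 5 of 5 day-60 libraries. They were picked on these same libraries, so this describes them and is no separate support. Below 10 RPM, miR-542-5p was also called.

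Markers of multiciliated cells and choroid plexus lay lower on day 60 in 6 of 7 members, with miR-449a-5p called and 3 lower when adjusted over the list alone; miR-34c-5p measured 1268 ± 1670 and 114 ± 66.1 RPM. The list did not pass as a set (adjusted p = 0.423). Of the other markers of cell types, neurons had 7 of 16 members above 0 (adjusted p = 0.945), astrocytes 11 of 18 (0.714) and oligodendrocytes and myelin 3 of 4 (0.714). Neural stem and progenitor cells had 6 of 17 (0.513), microglia and immune cells 3 of 10 (0.968) and vessels 2 of 6 (0.968). Pituitary and epithelium had 3 of 6 above 0 (adjusted p = 0.945), muscle 3 of 6 (0.968), erythroid cells 0 of 3 (0.714), liver 3 of 3 (0.423) and the HOX cluster 2 of 2 (0.423, with 1 higher over the list alone). The miR-17-92 list, with miR-363-3p called, had 7 of 18 above 0 (adjusted p = 0.586), the miR-30 family, with miR-30a-5p called, 7 of 11 (0.945). The miR-200 family had 2 of 4 (0.945), the miR-183 cluster 1 of 3 (0.968) and the miR-29 family 3 of 5 (0.968). The puberty and GnRH list had 9 of 12 (0.423) and the DLK1-DIO3 cluster 30 of 56 (0.775). Median, mean and set test differed in sign for the miR-29, miR-200, miR-183, vessel, pituitary and muscle lists.

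At an unadjusted p under 0.05, 87 miRNAs differed between day 1 and day 60. The count of 16 became 6 without replicate 2, 3 without replicate 3, 43 without replicate 4 and 31 without replicate 5 of day 1. It became 6, 9, 2 and 25 without replicates 2, 3, 4 and 5 of day 60, and 10 without replicate 3, 4 or 5 of day 120. Over all 20 fits with 1 library left out, let-7c-5p kept its call in 5, miR-324-5p in 6, miR-1388-3p in 6 and let-7c-3p in 11, and the other 8 miRNAs with values above in 15 to 19. Of the calls, 18.8% were upward, against 30.0% of 40 with median-of-ratios scaling, 35.3% of 34 with quantile scaling, 35.1% of 57 with edgeR and TMM and 38.4% of 86 with DESeq2. All 16 were among the calls of each of these 4, and 15 of them among those of edgeR on library size alone.

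From day 60 to day 120 no miRNA passed the test: limma, edgeR and DESeq2 called 0 each, with 13 miRNAs at an unadjusted p under 0.05 and a smallest adjusted p of 0.913. Of the 20 lists 3 passed with the preset correlation and 0 with an estimated one. The miR-29 family, repressor of collagens and DNA methyltransferases, lay higher in 5 of 5 members, with a median log2 fold change of 0.68 (set test adjusted p = 0.00205; adjusted p = 0.738 with an estimated correlation). miR-29a-3p measured 1125 ± 586 and 1653 ± 483 RPM (SD, n = 5), and miR-29b-3p 73.5 ± 48.9 and 133 ± 33.9 RPM. The DLK1-DIO3 cluster, a large imprinted run of miRNA genes active in neurons, lay lower in 39 of 56 members, median -0.14 (adjusted p = 0.00205; adjusted p = 0.871 with an estimated correlation). In it, miR-432-5p measured 1930 ± 486 and 827 ± 341 RPM, miR-382-5p 2302 ± 466 and 1195 ± 574, and miR-485-5p 913 ± 499 and 355 ± 135. These 3 members fell by more than the list median and are not typical of the list, in which 17 of 56 lay higher. The astrocyte list, which includes the miR-29 family, lay higher in 15 of 18 members (adjusted p = 0.0368; adjusted p = 0.738 with an estimated correlation), with miR-26a-5p at 44526 ± 17451 and 56543 ± 8008 RPM.

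No member of these 3 lists was called over all miRNAs or when adjusted over the list alone. The DLK1-DIO3 call ended without replicate 1 (adjusted p = 0.317) or 5 of day 60 (0.0654), with a range from 1.27e-07 to 0.317 over left-out libraries. The astrocyte call ended without replicate 1 (0.14), 4 (0.103) or 5 (0.0654) of day 60 or 3 (0.114) or 4 (0.0559) of day 120, with a range from 0.0115 to 0.14. The miR-29 call held in 20 of 20 such fits, all with the preset correlation. The erythroid miR-451-5p measured 198 ± 51.5 and 616 ± 416 RPM over the same interval, with 1 erythroid miRNA of 3 higher when adjusted over the list alone. The muscle list lay higher in 5 of 6 members, with a median of 0.74, and did not pass (adjusted p = 0.0782); miR-1 measured 928 ± 656 and 1571 ± 397 RPM. It passed without replicate 3 (adjusted p = 0.0115) or 4 (0.0197) of day 60, with a range up to 0.33 over left-out libraries. The vessel list (5 of 6 higher, adjusted p = 0.243) and the miR-30 family (7 of 11 higher, 0.141) passed without replicate 3 of day 60 (0.0175 and 0.0372, with ranges up to 0.634 and 0.39). The miR-183 cluster (3 of 3 lower, 0.463) passed without replicate 5 of day 120 (0.0174, with a range up to 0.959).

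**Figure D2:**
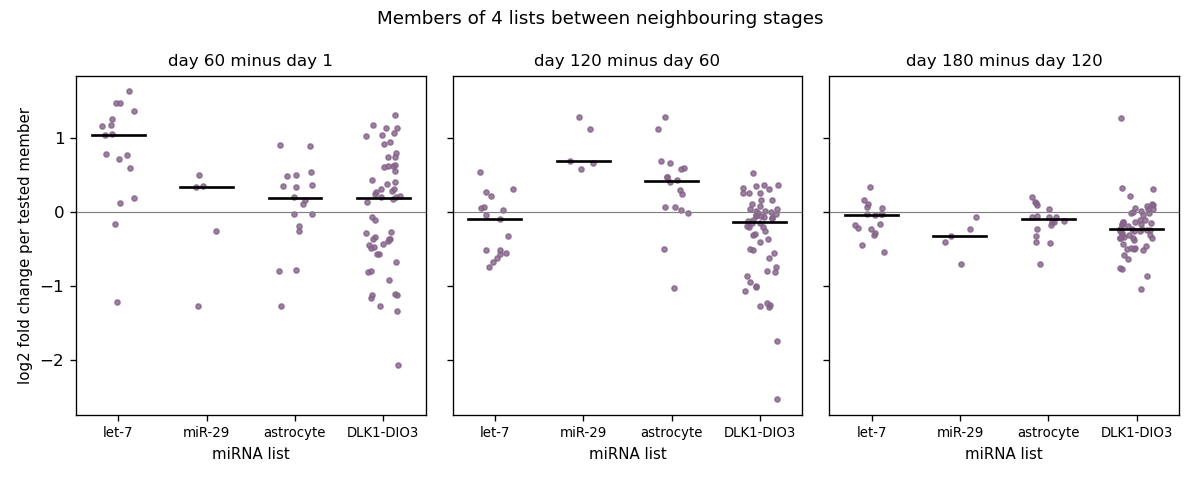
Log2 fold change of each tested member of the let-7, miR-29, astrocyte and DLK1-DIO3 lists between neighbouring stages, with 1 point per miRNA and a bar at the median of the list. The let-7 median is 1.04 between day 1 and day 60, and the miR-29 median 0.68 between day 60 and day 120; points are spread sideways for display only.

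Between day 120 and day 180 no miRNA and no list passed in the main fit of all 20 libraries. limma, edgeR and DESeq2 called 0 miRNAs each, 3 miRNAs had an unadjusted p under 0.05, and the smallest adjusted p was 0.997. The muscle list lay lower in 6 of 6 members (median -0.69 against -0.15 over all miRNAs, adjusted p = 0.0708), with miR-1 at 1571 ± 397 and 1426 ± 1245 RPM and miR-206, a skeletal muscle miRNA, at 258 ± 179 and 114 ± 47.2 RPM (SD, n = 5). With the preset correlation the muscle list passed without replicate 2 of day 120 (adjusted p = 0.0232) or replicate 1 (0.000952) or 3 (0.0201) of day 180, with a range up to 0.296. With an estimated correlation and all 20 libraries the set test gave it an adjusted p of 0.783. Below 0 lay 45 of 56 DLK1-DIO3 members (adjusted p = 0.365), 13 of 16 neuron markers (0.203) and 10 of 12 puberty and GnRH miRNAs (0.342). As in the muscle list, every tested member lay below 0 in the miR-200 family (4 of 4, adjusted p = 0.203), the miR-183 cluster (3 of 3, 0.302), the vessel list (6 of 6, 0.365), the erythroid list (3 of 3, 0.302), the miR-29 family (5 of 5, 0.365) and the HOX cluster (2 of 2, 0.302). The count of lists became 2 without replicate 2 of day 120, 5 without replicate 1, 1 without replicate 3 and 5 without replicate 4 of day 180, with the DLK1-DIO3 cluster (adjusted p = 0.000163, the lower end of a range up to 0.905), neurons (0.0161), oligodendrocytes and myelin (0.0175), the miR-200 family (0.0489) and pituitary and epithelium (0.0489) in the last. Besides muscle, the miR-200 family passed without replicate 2 of day 120 (0.0371). It passed with the miR-183, vessel and HOX lists without replicate 1 of day 180 (0.0486 each). Over left-out libraries the adjusted p of these lists other than muscle reached 0.85 to 0.95.

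Day 180 against day 1 spans the whole period. miR-101-3p rose 6.43-fold, from 1717 ± 957 to 11379 ± 7487 RPM (SD, n = 5; log2 fold change 2.68, SE 0.46, adjusted p = 0.000552), and miR-3955-3p rose from 4.68 ± 1.73 to 19.8 ± 9.73 RPM (1.82, SE 0.47, adjusted p = 0.0395). miR-363-3p fell 5.77-fold (log2 -2.53, SE 0.42, adjusted p = 0.000465), miR-493-3p 5.85-fold (-2.55, SE 0.52, adjusted p = 0.00355) and miR-449a-5p 8.96-fold (-3.16, SE 0.59, adjusted p = 0.00145). miR-412-5p, also of the DLK1-DIO3 cluster, fell from 835 ± 548 to 224 ± 121 RPM (-1.77, SE 0.48, adjusted p = 0.0395). All 6 lay beyond the day-1 mean in 5 of 5 day-180 libraries, on which they were also picked, so this is no separate support. miR-101-3p, miR-363-3p, miR-493-3p and miR-449a-5p kept their calls in 20 of 20 fits with 1 library left out, miR-3955-3p in 14 and miR-412-5p in 10.

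In all, 14 miRNAs changed between day 1 and day 180, 3 upward and 11 downward, 12 of them named. Below 10 RPM in both stages were let-7f-3p, higher, and miR-130b-3p, miR-412-3p, miR-542-5p, miR-496-3p and miR-665, lower. The let-7 family lay higher in 14 of 17 members, median 0.56, with 1 called and 1 when adjusted over the list alone (adjusted p = 0.000433; adjusted p = 0.711 with an estimated correlation). The astrocyte list lay higher in 13 of 18 members (adjusted p = 0.0403; adjusted p = 0.803 with an estimated correlation), none called over all miRNAs or over the list alone. Its call ended without replicate 1, 2 or 4 of day 1 and without replicate 1, 2 or 3 of day 180, with adjusted p from 0.00417 to 0.171 over left-out libraries. Of the DLK1-DIO3 cluster 5 members were called lower (miR-493-3p, miR-412-5p, miR-412-3p, miR-496-3p and miR-665) and 7 when adjusted over the list alone, with 42 of 56 below 0 (adjusted p = 0.163). With the preset correlation the cluster passed without replicate 5 of day 1 (adjusted p = 0.0124) or replicate 4 of day 180 (0.0027), with a range up to 0.459. With an estimated correlation and all libraries the set test gave it an adjusted p of 0.884. Multiciliated and choroid plexus markers lay lower in 6 of 7, with miR-449a-5p called (adjusted p = 0.173), and passed without replicate 4 of day 180 (0.0483, with a range up to 0.411). Oligodendrocyte and myelin markers lay higher in 3 of 4 (adjusted p = 0.173) and passed without the same library (0.0373, with a range up to 0.421). The liver list lay higher in 3 of 3 (adjusted p = 0.14) and passed without replicate 3 of day 1 (0.0341, with a range up to 0.28). Neural stem and progenitor markers lay lower in 10 of 17 (adjusted p = 0.505), with 1 called and 3 when adjusted over the list alone. Neuron markers lay lower in 13 of 16 (0.697). Every tested member lay below 0 in pituitary and epithelium (6 of 6, 0.697), the miR-200 family (4 of 4, 0.614), the miR-183 cluster (3 of 3, 0.355) and the erythroid list (3 of 3, 0.537).

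The count of 14 stood beside 86 miRNAs at an unadjusted p under 0.05, and the median of all log2 fold changes was -0.25, against -0.00285 after quantile scaling, so that falls are counted from a shifted centre. It became 7, 6, 7 and 31 without replicates 1, 2, 3 and 5 of day 1, 6 without replicate 5 of day 120, and 7, 9, 8 and 5 without replicates 1, 3, 4 and 5 of day 180. Of the calls 21.4% were upward, against 48.0% of 25 with quantile scaling and 8.33% of 48 with edgeR on library size alone. edgeR with TMM shared 11 of the 14 calls, and edgeR on library size alone shared 13.

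By day 120, miR-101-3p already stood 5.99-fold above day 1 (log2 fold change 2.58, SE 0.46, adjusted p = 0.00146), and 14 miRNAs had changed, 6 upward and 8 downward, 10 of them named. Among them, named after their values were seen, miR-374a-5p rose from 78.7 ± 68.2 to 256 ± 52.1 RPM (1.99, SE 0.55, adjusted p = 0.0434) and miR-340-5p from 682 ± 275 to 1912 ± 776 RPM (1.49, SE 0.42, adjusted p = 0.0451). miR-3955-3p and let-7f-3p were higher, and miR-363-3p, miR-493-3p, miR-449a-5p, miR-412-3p and miR-542-5p lower. The let-7 family lay higher in 15 of 17 members, median 0.77, with 1 called and 4 when adjusted over the list alone (adjusted p = 0.00165; adjusted p = 0.583 with an estimated correlation). The astrocyte list (13 of 18 higher, adjusted p = 0.0795) passed without replicate 5 of day 1 (0.0135) or replicate 2 of day 120 (0.0317), with a range up to 0.135. The multiciliated and choroid plexus list (6 of 7 lower, 0.119) passed without replicate 2 of day 120 (0.0317, with a range up to 0.296). The median of all log2 fold changes was -0.12. There were 93 miRNAs at an unadjusted p under 0.05. The count of 14 became 8, 25 and 29 without replicates 2, 4 and 5 of day 1, and 7 and 8 without replicates 3 and 4 of day 120. Upward calls made up 42.9%, against 48.7% of 39 with quantile and 36.1% of 36 with median-of-ratios scaling, 25.6% of 43 with edgeR and TMM, 17.1% of 35 with edgeR on library size alone and 27.0% of 74 with DESeq2. edgeR on library size alone shared 12 of the 14 calls.

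The comparisons with day 1 share its 5 libraries. Days 60 and 120 shared 6 calls of the same direction, days 60 and 180 shared 6, and days 120 and 180 shared 10. With no effect, 100 simulations gave means of 0, 0 and 0.05 shared calls and at most 0, 0 and 5. Independent lists would share 0.295, 0.367 and 0.256. Neither shows what the shared libraries add once real calls exist. With the day-1 libraries split between the comparisons in 20 fits, 1.4, 1.9 and 2.3 calls were shared on average. Each comparison then held fewer day-1 libraries, which can also lower the number of calls to share. miR-363-3p, miR-493-3p, miR-449a-5p and miR-542-5p were the 4 named among 6 miRNAs called in all 3 comparisons.

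Between day 60 and day 180, no single miRNA passed in limma, edgeR or DESeq2 (20 at an unadjusted p under 0.05; smallest adjusted p 0.845), while the DLK1-DIO3 cluster lay lower in 54 of 56 members, median -0.46 against -0.15 over all miRNAs (adjusted p = 2.14e-05; adjusted p = 0.803 with an estimated correlation). miR-432-5p measured 1930 ± 486 RPM on day 60 and 779 ± 193 on day 180 (SD, n = 5), miR-382-5p 2302 ± 466 and 1072 ± 280, and miR-485-5p 913 ± 499 and 307 ± 162. In these 3 members the mean fell by more than the list median. The mean over the cluster lay below the day-60 mean in 4 of 5 day-180 libraries, and the call with the preset correlation held in 20 of 20 fits with 1 library left out. With an estimated correlation of 0.462 between members, neither that call nor the 54 of 56 rests on independent members. Other lists also lay lower without passing: the miR-183 cluster in 3 of 3 members (median -1.31, adjusted p = 0.144) and the miR-200 family in 4 of 4 (-0.80, 0.277). Pituitary and epithelium, a list that shares members with that family, lay lower in 5 of 6 (-0.80, 0.301) and the HOX cluster in 2 of 2 (-0.73, 0.301). The miR-183 cluster passed without replicate 2 of day 60 (adjusted p = 0.0313) or replicate 1 of day 180 (0.0455), with a range up to 0.391. The let-7 family lay lower on day 180 in 11 of 17 members (median -0.53, adjusted p = 0.309) and passed without replicate 3 of day 180 (0.0245, with a range up to 0.714). The miR-29 family lay higher in 5 of 5 members (adjusted p = 0.0161; adjusted p = 0.803 with an estimated correlation) and the astrocyte list in 13 of 18 (adjusted p = 0.0161; adjusted p = 0.803 with an estimated correlation). None of the members of these 3 lists was called over all miRNAs or when adjusted over the list alone. The miR-29 call ended without replicate 3 of day 60 (adjusted p = 0.251) or replicate 2 (0.0834) or 4 (0.116) of day 180, with a range from 0.00561 to 0.251 over left-out libraries. The astrocyte call ended without replicate 4 of day 60 (0.0896) or replicate 3 of day 180 (0.118), with a range from 0.00455 to 0.118. The directions of the let-7, miR-29, astrocyte and DLK1-DIO3 lists kept their sign under each scaling in the comparisons in which they passed.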

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

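Of the tests in this part, those of miR-122 against carried-over reads and against blood, of replicate 2 of day 1 against a wrong stage and against a few dominant miRNAs, and of scaling were chosen only after the result was seen. The pooled comparison of day 1 with the 3 later stages and the covariate for the library axis were added after the data were seen.

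miR-122 was higher in the 3 later stages together than on day 1 by 2.79 log2 units (SE 0.66, adjusted p = 0.00911). In the single comparisons with day 1, limma called it for day 60 only, and not for day 120 or day 180. The day-60 call was lost without replicate 4 of that stage (limma adjusted p = 0.0559). Retained red cells are argued against, since the erythroid list moved by -0.41 (SE 0.34, upper bound 0.28). This holds if red cells carry these miRNAs alike at each age. The list holds red-cell miRNAs only, so that it cannot decide on plasma, and blood as a source stays open to that extent. Carried-over reads from outside the tissue stay open and cannot be told apart from expression: 12 of 15 later libraries lay within 25% of their median of 124 RPM, a spread at percentile 1.55 of 129 miRNAs of like level, but that test was made on a miRNA picked for this shape and decides nothing. Replicate 4 of day 60 held 2540 RPM against 124 to 233 in the rest of its stage, and replicate 5 of day 180 held 10.9 RPM against 124 to 142. Age and sources not tested here remain possible.

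Replicate 2 of day 1 differs from every other library in its whole profile. Its depth is argued against as the cause, because after thinning all libraries to its 4017937 reads its median Spearman correlation with the others was 0.873, against 0.917 for the next lowest. Its highest median correlation with a later stage was 0.874, where the libraries of those stages reached at least 0.939. With its own stage it was 0.891, where the other day-1 libraries reached at least 0.922. It thus lay nearest to day 1 but fell short of every stage, so that this test cannot decide on a wrong stage label. Its 10 most abundant miRNAs held 53.8% of its reads, below the median library's 69.3%, which argues against a few miRNAs taking most of the reads. What sets it apart is open, GC content included, which was not analysed here, and a difference of the animal or dissection was not tested.

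The differences between day 1 and the later stages were set against this library and against scaling. Without it the pooled comparison called 18 miRNAs in place of 44, and all 18 (100%) remained with the library axis as a covariate. In the libraries left, scores on that axis averaged 0.0364 ± 0.172 (SD) on day 1 and -0.0251 ± 0.176 in the later stages. With so small a difference the covariate could remove few calls, so that this outcome decides little. It says nothing of the calls lost with the library. In the single comparisons 6 of 6 calls remained for day 60, 5 of 6 for day 180 and 5 of 8 for day 120, so that the axis stays open for part of the day-120 calls. At least 90.9% of the 44 calls remained under median-of-ratios and quantile scaling, which argues against scaling. Age, and anything else that differed between newborn and older animals at collection, stays open as untested.

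Chance in the grouping of libraries was examined with 100 splits per count, the real one included. For the F test (8 miRNAs, highest other split 3), only the real split gave as many calls. The same held for day 120 against day 1 (14, highest other 2) and for the pooled comparison (44, highest other 1). For the F test and for day 120 against day 1 this argues against chance. The pooled comparison was added after the data were seen, so for its count the splits cannot decide. For day 180 against day 1 (14 miRNAs), 2 splits gave as many calls, the real one included, and the highest other gave 16. For day 60 against day 1 (16 miRNAs), 4 splits did, and the highest other gave 87. Chance is not excluded for these 2 counts. The splits say nothing for day 120 against day 60, day 180 against day 120 or day 180 against day 60: the real count was 0, so that all 100 splits are as large by construction, and the highest others were 1, 2 and 33. The splits with 87 and 33 calls point to a structure of the samples. The first put replicates 1, 2 and 3 of day 1 with replicates 1 and 5 of day 60. Their factors under median-of-ratios scaling ran from 1.02 to 1.91, against 0.718 to 1.09 in the libraries opposite. The second put replicates 1 and 4 of day 180 with replicates 2, 3 and 4 of day 60. There the factors ran from 0.678 to 1.09, against 0.860 to 1.23. The 2 sides thus differed in scale, with some overlap, and whether this makes those calls was not tested.

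Within groups of 5 libraries, 19 of 224 groups held a library far from the rest, where chance gives about 11.2. In RPM, the other such values were 3406 for let-7c-5p in replicate 3 of day 1, 0.717 for miR-874-5p in replicate 1 of day 180, 2.57 for miR-1388-3p in replicate 1 of day 120, 144 for miR-1271-5p in replicate 2 of day 120, 8452 for miR-30a-5p in replicate 5 of day 180 and 1.74 for miR-3955-3p in replicate 2 of day 1. Among abundant miRNAs and list members they were 237600 for miR-9-5p in replicate 1 of day 120, 172500 for miR-143-3p in replicate 1 of day 180, 29570 for let-7g-5p in replicate 3 of day 60, 939 for let-7d-5p in replicate 5 of day 60, 704 for miR-192-5p in replicate 4 of day 180, 1662 for miR-34c-5p in replicate 2 of day 120, and 28.8 for miR-200c in replicate 4 of day 60. In replicate 2 of day 1, miR-200c stood at 498 RPM against 3.53 to 11.6 in the rest of its stage. Depth was far below the rest of its stage in replicate 2 of day 1, at 4018000 reads, and in replicate 3 of day 60, at 4353000 reads.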

How the results depend on the processing

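The fit with the library axis as a covariate was added after the data were seen; the other alternatives were planned. The 0 calls between later stages stayed at 0 in every alternative run, and no fold change of a miRNA named by the rule reversed in any; other named miRNAs were not followed through all of these. The count of 16 for day 60 against day 1 became 9 without a filter, 40 with median-of-ratios and 34 with quantile scaling, 4 with only the 2 stages compared, 57 with edgeR and TMM, 62 with edgeR on library size alone and 86 with DESeq2. For day 180 against day 1, 14 became 7 with a pseudocount of 0.1, 8 without a filter, 5 with a filter at 10 RPM (301 miRNAs tested), 23 with median-of-ratios and 25 with quantile scaling, 5 with only the 2 stages, 22 with edgeR and TMM, 48 on library size alone and 61 with DESeq2. For day 120 against day 1, 14 became 36 with median-of-ratios and 39 with quantile scaling, 4 with only the 2 stages, 43 with edgeR and TMM, 35 on library size alone and 74 with DESeq2. The 8 miRNAs of the F test became 30, 28, 39, 53 and 90 with median-of-ratios scaling, quantile scaling, edgeR with TMM, edgeR on library size alone and DESeq2. The 44 of the pooled comparison became 28 with a filter at 10 RPM, 67 with quantile scaling, 91 with edgeR and TMM, 101 on library size alone and 108 with DESeq2, and the other settings gave 43 to 59. The 3 in strict order of age became 5 with a pseudocount of 0.1, 10 with median-of-ratios and 9 with quantile scaling. With the library axis as a covariate and without replicate 2 of day 1, the counts against day 1 were 6 for day 60, 5 for day 180 and 6 for day 120, where leaving out that library alone gave 6, 6 and 8 (6, 5 and 5 shared); the pooled count was 26 against 18. Fewer libraries in the fit can account for the counts with only the 2 stages; for the rest the cause was not tested. Leaving out each library in turn gave 2 to 43 calls for day 60 against day 1, lowest without replicate 4 of day 60 and highest without replicate 4 of day 1; 5 to 31 for day 180 and 7 to 29 for day 120 against day 1; 5 to 16 for the F test; 2 to 6 in order of age; and 18 to 60 for the pooled comparison. With an estimated correlation the lists called went to 0 in each comparison, from 1 for day 60, 2 for day 180 and 1 for day 120 against day 1, and from 3 for day 120 and 3 for day 180 against day 60. Leaving out each library gave 1 to 1, 1 to 5, 1 to 3, 1 to 6 and 2 to 4 lists for these, and 0 to 5 for day 180 against day 120. The replicate numbers do not pair the libraries: over 30 pairs with the same number the mean correlation of deviations was 0.0452 and the lowest -0.714, 11 pairs exceeded 0.1, and 4 of 20 libraries correlated best with their own number. The replicate block called the muscle list for day 180 against day 120 (1 list in place of 0; adjusted p = 0.0206) and for day 120 against day 60 (4 in place of 3; 0.0485), moved no other count by over 1.5 times and kept all 16, 14 and 14 calls against day 1. Depth limits what is detectable below 0.747 RPM in the shallowest library.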

Other observations

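The pooled comparison of day 1 with the 3 later stages, the arm ratios and the co-variation of the DLK1-DIO3 members were analysed only after the data were seen, and the test of co-variation also after its result was seen; miRNAs in this part are named after their values were seen.

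Set against the 15 later libraries together, day 1 differed in 44 miRNAs, 10 of them higher and 34 lower in the later stages, around a median of all log2 fold changes of -0.14. Of the calls, 20 of 59 were higher with median-of-ratios scaling and 28 of 67 with quantile scaling. miR-101-3p rose from 1717 ± 957 RPM (SD, n = 5) to 8600 ± 5557 (SD, n = 15; log2 fold change 2.23, SE 0.38, limma adjusted p = 0.000394), above the day-1 mean in 15 of 15 later libraries. let-7a-3p rose from 29.7 ± 11.8 to 75.8 ± 33.1 RPM (1.28, adjusted p = 0.0311), among 4 called members of the let-7 family (set test adjusted p = 7.91e-05; adjusted p = 0.571 with an estimated correlation). miR-199a-5p, a miRNA of mesenchymal and vascular cells, fell from 179 ± 128 to 53.3 ± 26.6 RPM (log2 -1.48, adjusted p = 0.0334). miR-363-3p and miR-493-3p were lower than the day-1 mean in 15 of 15 later libraries each. Such counts come from the libraries on which these miRNAs were picked and are no separate support. Without replicate 2 of day 1 the count was 18, all among the 44, and without replicate 3 it was 23. Without replicate 2, let-7a-3p (adjusted p = 0.12) and miR-199a-5p (adjusted p = 0.115) lost their calls, while miR-101-3p (0.0027), miR-363-3p (0.00142) and miR-493-3p (0.00885) kept theirs.

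The hypothesis that the arms of 1 hairpin change by different amounts with age was tested on 120 hairpins with both arms measured, and 29 passed for a changed ratio of the 5p to the 3p arm (limma, adjusted over the 120; 48 at an unadjusted p under 0.05). The ratio was higher in the later stages in 12 and lower in 17. An arm near 1 RPM can hardly fall on the log2(RPM + 1) scale, so that a change of both arms can then appear as a changed ratio. With both arms at 10 RPM or more in the mean, 18 of 67 hairpins passed, 8 to 23 without any 1 library, with 11 without replicate 2 and 8 without replicate 3 of day 1. Among these, for miR-340 the 5p arm changed by 1.13 log2 units and the 3p arm by -0.13 (ratio 1.26, SE 0.30, adjusted p = 0.00633 over the 67). For miR-30a the 5p arm changed by -1.11 and the 3p arm by 0.51 (ratio -1.61, SE 0.44, adjusted p = 0.0132). For miR-493 the 3p arm changed by -2.23 and the 5p arm by 0.09 (ratio 2.32, SE 0.66, adjusted p = 0.0163). Over all 120, 22 passed without replicate 2 of day 1, of which 17 were among the 29, and 19 to 32 without any 1 library. Of 100 splits of the libraries only 1, the real one, gave as many as 29, and the highest other gave 10. The pooled grouping was chosen after the data were seen, so the splits cannot decide on chance here. The arms may be processed or stabilised differently with age, a hypothesis these ratios bear on but do not single out.

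Members of the DLK1-DIO3 cluster varied together between animals of 1 stage: the median pairwise correlation of the 56 tested members' deviations from their stage means was 0.508, above all 1000 random lists matched on level (median 0.172, highest 0.334). It was 0.514 without replicate 2 of day 1 (highest random list 0.309) and 0.543 in the 15 later libraries alone (0.328), and 0.527 with 1 arm for each of the 40 hairpins. In the ARS1.2 annotation the 40 hairpins lie in 1 run of 45 miRNA genes; miR-3955, whose 3p arm was higher in the later stages, is 1 of 3 genes of that run outside the list. Shared regulation of the run may contribute, and so could differences in dissection between animals, which were not tested.

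Among 70 miRNAs with a mean of at least 1000 RPM, miR-7-5p had the largest spread between animals of a stage, with a within-stage SD of 1.35 log2 units against a median of 0.754, and values from 9515 to 304600 RPM. The hypothesis that it follows pituitary and epithelial tissue in the sample found no backing. Over the 20 libraries its mean within-stage correlation with 4 other members of that list was -0.0228 (permutation p = 0.924, 100000 resamples). It was -0.173 without the 2 libraries farthest from the miR-7-5p median, and the mean Spearman correlation was 0.0154 (permutation p = 0.942). These 4 members are the tested miR-200 family, so that the test speaks for 1 family and not for the tissue as a whole. Only 1 such relation was computed.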
